A study of Rattus norvegicus with 6 samples.

How the data were processed

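ATAC-seq libraries of primary rat BMSCs were made from about 50,000 cells each and amplified for 11 PCR cycles, and were sequenced as single-end reads of 50 bases, per the labels' protocols. The deposited file is 1 table of raw counts per peak and library, with whole numbers and no normalization. Per the submitters' processing notes, Bowtie2, MACS2, deepTools, DESeq2 and the genome build rn6 were used by the authors, with no versions or roles. The counting tool, the read filters, any shift of reads for the transposase, the removal of duplicates or mitochondrial reads, and whether peaks were called on pooled libraries are not given in the sources used here. Peaks are numbered up to 169,607, and 3099 numbers below that are absent from the table.

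Libraries were assigned to the hypoxia group (3) or the control group (3) by their titles, and table columns to libraries by the library names in the labels. The labels do not state the oxygen level of the control culture, nor whether the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. PCR duplicates cannot be told from separate molecules in a count table, so the intervals and tests cover counting error and the spread between libraries only. The RNA-seq part of the study was not analysed here.

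The main comparison used edgeR 4.0.16 in R 4.3.3 on the counts as deposited: TMM scaling (factors 0.991 to 1.01), the default expression filter (minimum count 10, minimum total 15), robust dispersion estimation and the two-sided quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg over the 118,069 peaks that passed the filter (70.9%), and an adjusted p under 0.05 counted as a call. Standard errors of log2 fold changes were derived from the fold change and its test statistic. CPM values used totals scaled by TMM, and a prior count of 2 was added where log2 CPM was used for correlations and principal components. Library pairs were also compared by a chi-square per peak, over the tested peaks outside the strongest 1%. It is 1 for independent single reads and 2 for reads counted in pairs. It was 2.18 to 2.48 over the 15 pairs, so no library was a copy of another. Comparisons of a single value per library used exact permutation tests.

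Strong peaks were the 1% with the highest mean CPM (27.5 or more). Windows summed the counts over 50 consecutive peak numbers, and runs summed those of at least 5 strong peaks with gaps of at most 10 numbers. Windows and runs were tested with edgeR using the total counts and TMM factors of the whole table. The unpaired share of a library was estimated from the share of odd counts outside the strong peaks, taking unpaired reads as Poisson with one mean for all peaks. Strong peaks, windows, runs, counts halved to pairs, thinning by pairs, the repeats of the library similarity without thinning and the unpaired share were chosen after seeing the data; the test of single peaks, its filter and its other alternatives were fixed before the data were examined.

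The rule for naming peaks, in its form for peaks without genes, took up to 10 rises and 10 falls with the largest change among called peaks with separated groups and a mean signal at or above the median. Only A_120271 met it. As the file does not pair peak identifiers with genes or coordinates, at most 2 identifiers are printed in each direction, and those of A_41666, A_64827 and A_24676 fall outside the rule. The peak identifiers are numbered labels that name no gene. The planned tests of gene lists, promoter against distal peaks, motifs, chromosomes, peak width and GC content need coordinates and an rn6 sequence and were not run.

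The procedure was tested on simulated counts drawn with the means, depths and dispersions of these libraries. The simulated counts did not come in steps of 2. Over 118,069 simulated peaks of this comparison, 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold. Of these changes 0%, 4.48% and 40.9% were called. With as many changes placed in the strongest 1%, these values were 4.48%, 65.7% and 100%. Over 3393 simulated windows, 76.1% of 1.25-fold and 100% of 1.5-fold changes were called, with 67 windows changed at each of these folds. The shares called depend on how many features change among those tested. This number was not varied, so the shares for peaks and windows cannot be set against each other. Over 76 simulated runs, 6 of 6 changes of 1.5-fold were called. These runs were simulated and tested on the totals of the runs alone, unlike the real runs. Shifts shared by all strong peaks of a library are therefore left out, and the real test may detect less. Alternatives were DESeq2 1.42.0 size factors and its Wald test, limma 3.58.1 with voom, total-count scaling, loess offsets by mean signal (span 0.3, in place of GC offsets), no filter, a minimum of 50 counts in 3 libraries, an adjusted p under 0.01, a test against 1.5-fold, the replicate number as a block, and leaving out each library. Figures were drawn with Python 3.11.15.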

Results

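Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in primary rat bone marrow stromal cells (BMSCs, the adherent marrow cells that can form bone, cartilage and fat). Cells kept at 1% oxygen for 7 days made up the hypoxia group, and cells under normal culture conditions made up the control group, with 3 libraries in each. The question posed by the series was which open regions change when these cells lack oxygen, as background to hypoxia-associated bone loss and the transcription factor SP1. The deposited table held 166,508 peaks with a raw count in each of the 6 libraries, and no coordinates or gene names. Regions are therefore described here by peak identifier, signal class and position in the numbering, and no statement is made about any gene, promoter or motif.

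The hypoxia libraries held 3,634,436, 3,198,644 and 3,061,636 counts in peaks, and the control libraries 1,964,045, 1,704,504 and 1,936,218. Mean depth was 1.77 times higher in hypoxia, with every hypoxia library deeper than every control library (two-sided exact permutation p = 0.1, the smallest possible with 3 against 3). The median peak held 17, 15 and 14 counts in the hypoxia libraries and 9, 8 and 9 in the control libraries. Peaks with 0 counts made up 0.406% ± 0.139 of the table in hypoxia and 2.82% ± 0.54 in control (SD, n = 3 each). Even counts outnumbered odd ones in every library, at 63.8% to 82.0% of peaks against 50.0% for reads counted singly. The even share was 65.0% ± 1.33 in hypoxia and 74.98% ± 6.16 in control, with no overlap between the groups (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible), so it was confounded with the group as depth was. Among peaks of 100 counts or more the even share was 52.1% to 54.5%.

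**Figure D1:**
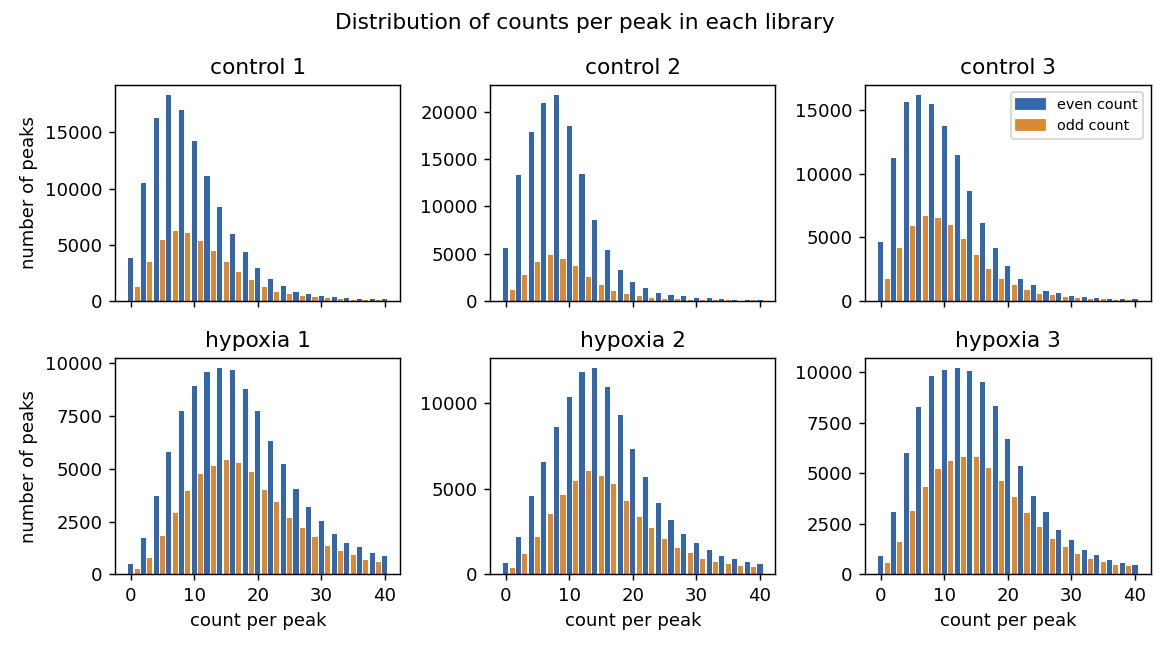
Number of peaks (vertical axis, a separate scale per panel) at each count from 0 to 40 (horizontal axis) in the 3 control and 3 hypoxia libraries, with even counts in blue and odd counts in orange. Even counts stand above the odd counts beside them in all 6 libraries, most clearly in control 2, where 82.0% of peaks had an even count.

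Of the 118,069 peaks tested between cells kept for 7 days at 1% oxygen and control cells, 1 passed the threshold. Peak A_120271 rose 5.97-fold in hypoxia, from 2.60 ± 1.51 to 15.4 ± 3.01 CPM (normalised counts, scaled to the library's total; SD, n = 3 each). Its log2 fold change was 2.58 (SE 0.47; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0379). It held 56, 33 and 41 counts in the hypoxia libraries and 2, 6 and 4 in the control libraries. No peak passed the threshold as lower in hypoxia, and the 95% range of uncertainty around a typical peak's log2 fold change was ± 1.01. When 67 of the peaks were simulated with a 2-fold change, 4.48% of them were called. A 2-fold change in so few single peaks would thus mostly be missed at this depth. Larger numbers of changed peaks were not simulated.

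At an unadjusted p under 0.05 there were 6621 peaks, 5.61% of those tested, of which 3659 were higher and 2962 lower in hypoxia. In 11.6% of the tested peaks all 3 hypoxia libraries lay on one side of all 3 control libraries. Chance gives 10% if all libraries have the same spread. The hypoxia libraries were deeper, so 10% may not hold here and 11.6% is not read as an excess. DESeq2 called 0 peaks, with 5754 at an unadjusted p under 0.05, while limma-voom called 27, of which 17 were higher and 10 lower. The count rested on single libraries too: 25 peaks passed without control 2, 9 without hypoxia 3, 4 without control 1, and 0 without control 3 or without hypoxia 1.

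The other peaks given here had the smallest p in their direction, with at most 2 peaks printed per direction. They did not pass the threshold and were chosen after their values were seen. In all, 5 peaks had an adjusted p under 0.1 by edgeR, so some with a smaller p than A_24676 are not printed. Peak A_41666 had 21.1 ± 1.75 CPM in hypoxia and 5.60 ± 1.24 in control, a 3.70-fold higher mean signal by the fitted model (adjusted p = 0.0582 by edgeR). Peak A_64827 had 6.40 ± 0.90 CPM in hypoxia and 21.4 ± 5.73 in control, a fitted 3.30-fold lower signal (adjusted p = 0.0692 by edgeR). Peak A_24676 had 2.59 ± 0.57 CPM in hypoxia and 13.0 ± 3.79 in control, a fitted 4.90-fold lower signal (adjusted p = 0.116 by edgeR). In each of these 4 peaks the 3 hypoxia libraries lay on one side of the 3 control libraries. The call of A_120271 was lost in edgeR without control 1 (adjusted p = 0.150), control 3 (0.121) or hypoxia 1 (0.186), and under DESeq2 (0.0773) and limma-voom (0.986). It was also lost in edgeR with the hypoxia libraries thinned to control depth (adjusted p = 0.794), with no filter (0.0924), in the test against 1.5-fold (0.601) and with the replicate number as a block, without (0.156) or with loess offsets (0.0752). Its adjusted p over all settings ranged from 0.00285 to 0.986. A log2 fold change of at least 2.24 was fitted for it in every setting that tested it. Among the settings other than the main one, A_41666 passed in 5 of 21, A_64827 in 5 of 20 and A_24676 in 0 of 20.

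**Figure D2:**
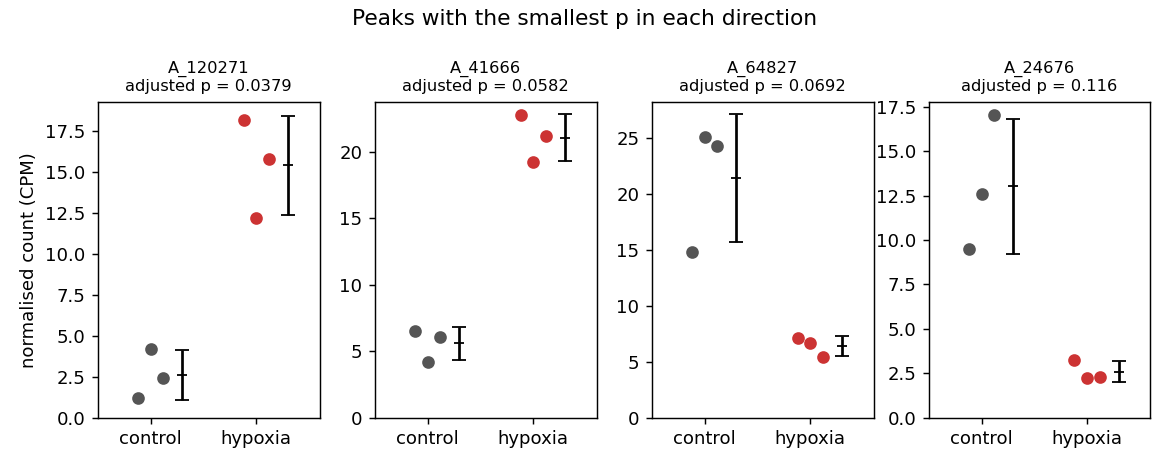
Normalised counts (CPM, vertical axis starting at 0, a separate scale per panel) of 4 peaks in the control libraries (grey points) and the hypoxia libraries (red points); the bars beside the points give mean ± SD, n = 3. The groups do not overlap in any of the 4 peaks, and A_120271 alone has an adjusted p under 0.05, at 0.0379.

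**Figure D3:**
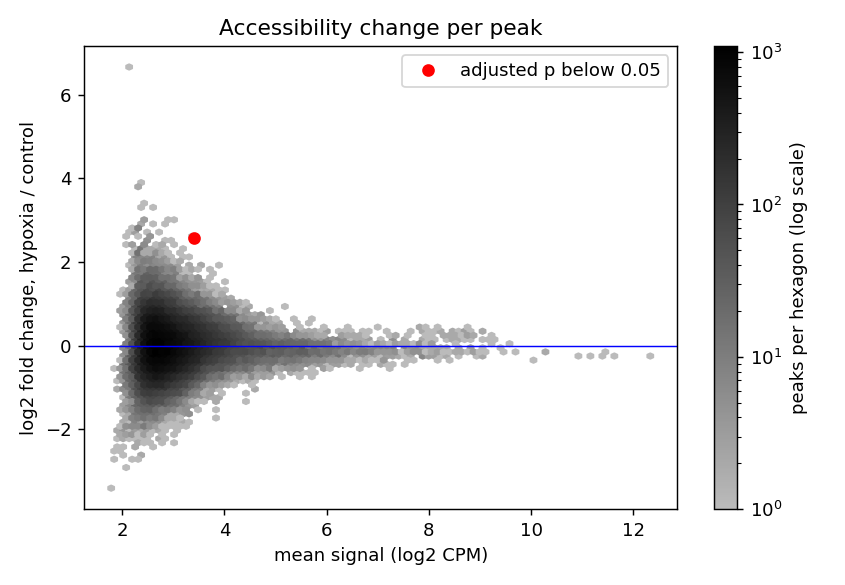
Log2 fold change of hypoxia over control (vertical axis) against mean signal in log2 CPM (horizontal axis) for the 118,069 tested peaks, shaded by the number of peaks per hexagon on a log scale. The spread narrows as signal rises, and the red point marks A_120271 at a log2 fold change of 2.58.

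The 1666 peaks that form the strongest 1% of the table had a median log2 fold change of -0.09, and 68.4% of them had a lower fitted signal in hypoxia. This median was -0.01 with loess offsets by mean signal, with or without the replicate block, -0.04 without control 1 and -0.16 without control 2. Of these peaks, 202 (12.1%) had an unadjusted p under 0.05, with 60 higher and 142 lower; the split with control 2 and hypoxia 3 exchanged gave 11.7%. In the 29,517 weakest tested peaks the share was 3.17% and in the 29,518 strongest 7.84%. The median standard error of the log2 fold change was 0.66 and 0.38. As precision differed between them, these shares do not rank the classes by how often they differed. The cause of the difference in share was not tested. Tested alone, this class gave 8 peaks past the adjusted threshold, of which 5 were higher and 3 lower in hypoxia, and 2 other splits of the 6 libraries gave more. The class took 13.2% ± 0.32 of all counts in hypoxia and 14.0% ± 0.77 in control, a difference that was not separable from the spread between libraries (SD, n = 3 each; two-sided exact permutation p = 0.3).

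Counts were also summed over neighbouring peak numbers, which stand for broad regions only if the numbering follows the genome. None of these windows passed the threshold in edgeR. The signal of neighbouring peak numbers was correlated across peaks (Pearson r = 0.447 at a distance of 1, 0.275 at 10 and 0.003 at 1000; -0.004 with the numbers shuffled), where peaks are not independent replicates. Log2 fold changes of single peaks correlated at 0.024 at a distance of 1. The table does not state what order the numbers follow. Across 3393 windows of 50 peak numbers, log2 fold changes ran from -0.31 to 0.35, and 98.6% of windows lay within 0.25 of 0. The smallest adjusted p was 0.185. In all, 374 windows (11.0%) had an unadjusted p under 0.05, of which 241 were higher and 133 lower in hypoxia, and neither DESeq2 nor limma-voom called any, with 0 each. The 95% half-width of a typical window was 0.17 on the log2 scale, or 1.13-fold. Without control 2, 15 windows passed, without hypoxia 3, 3 windows, and without control 3, 1 window.

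Strong peaks stood together in 76 runs in the numbering, which held 1284 peaks and 11.1% of all counts. Of these runs 60 had a lower and 16 a higher fitted signal in hypoxia, with a median log2 fold change of -0.09. The 83-peak run that contains the strongest peak of the table had 22,833 ± 1204 CPM in hypoxia and 26,640 ± 2150.3 in control, with a log2 fold change of -0.22 (SE 0.08; adjusted p = 0.128 by edgeR; SD, n = 3 each). That run held 2.42% of all counts, and a 62-peak run came next with 1.10%. The 62-peak run had 11,599 ± 275 CPM in hypoxia and 10,037 ± 599 in control, with a log2 fold change of 0.21 (SE 0.08; adjusted p = 0.128 by edgeR; SD, n = 3 each). The 98-peak run, which had more peaks than the others, had a log2 fold change of -0.09 (SE 0.08). In edgeR 0 runs passed, with 10 at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 3. Leaving out control 2 raised the count to 30 runs, 4 higher and 26 lower.

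**Figure D4:**
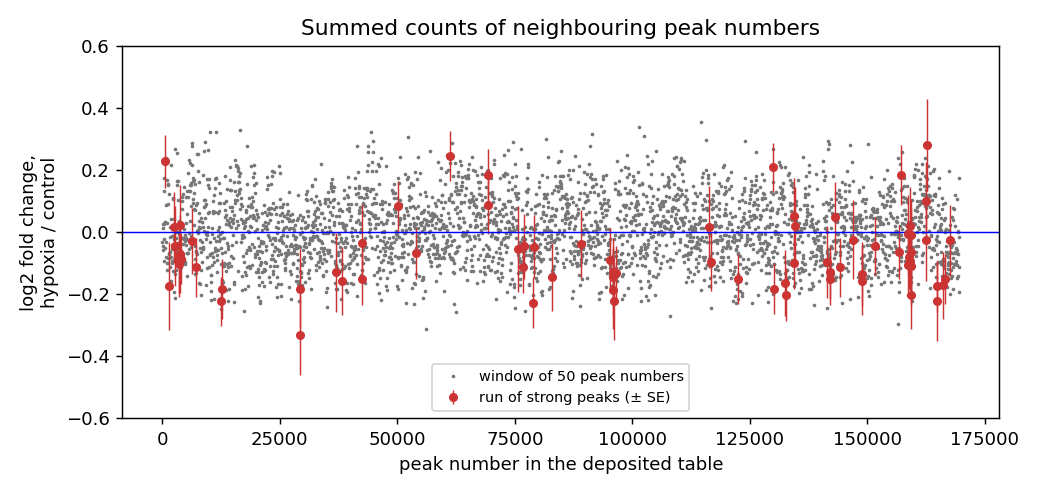
Log2 fold change of hypoxia over control (vertical axis) for windows of 50 peak numbers (grey points) and for 76 runs of strong peaks (red points with ± 1 SE), placed by peak number in the deposited table (horizontal axis). Windows lie between -0.31 and 0.35 along the whole numbering, and 60 of the 76 runs lie below 0.

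Averaged over both groups, libraries of one group were more alike than libraries of different groups by a small margin, which depended on the measure and on the group. After all libraries were thinned to equal depth, Pearson correlations of log2 CPM across peaks were 0.400 to 0.473 within control, 0.431 to 0.458 within hypoxia and 0.379 to 0.464 between the groups. The mean within-group value exceeded the mean between-group value by 0.0113, the highest of the 10 possible splits of the 6 libraries (exact permutation p = 0.1, the smallest possible). In the strongest 1% of peaks, without thinning, the excess was 0.00190 and 7 of the 10 splits gave one as large in size (exact permutation p = 0.7). These correlations were 0.924 to 0.945 within control, 0.965 to 0.970 within hypoxia and 0.943 to 0.953 between the groups. The chi-square per peak was lower within groups by a difference of -0.0710, and 2 of the 10 splits gave one as large in size (exact permutation p = 0.2). Its mean was 2.24 within control, 2.40 within hypoxia and 2.39 between the groups, so the control pairs alone were lower. Libraries were not thinned for it, and the strongest 1% of peaks were left out of it. The common biological coefficient of variation was 0.301 on counts as deposited, a dispersion of 0.0908. On counts halved to pairs the dispersion was 0.013, so part of the 0.301 may be counting noise. The first principal component of the peaks, 28.6% of the variance, set control 2 apart from the other 5 libraries. The second, 23.5% of the variance, had control 3 at 186 and every other library at 37.2 or lower. The third, 20.4% of the variance, separated the groups, with scores of 68.2, 75.9 and 76.5 in hypoxia and -163, -23.7 and -34.1 in control. Control 1 lay furthest from the rest on it. The control libraries were also the shallower ones, so this separation cannot be told apart from depth. On the first component of the window sums, 41.5% of the variance, control 1 (-4.98), control 3 (-4.95) and hypoxia 3 (-1.03) lay on one side and control 2 (2.84), hypoxia 1 (3.87) and hypoxia 2 (4.26) on the other. The estimated share of unpaired counts parted the libraries into the same sets, at 3.88%, 4.40% and 3.99% in the first 3 and 2.44%, 3.16% and 3.27% in the others. So did the share of counts in the strongest 1% of peaks, at 14.41%, 14.399% and 13.589% against 13.075%, 13.125% and 12.974%. Those peaks are part of the window sums.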

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

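The settings with halved, thinned or restricted counts, the unpaired share, the similarity of libraries without thinning, windows and runs were chosen after seeing the data. Against 1 called peak, 0 were called with no filter, under DESeq2, at an adjusted p under 0.01, in the test against 1.5-fold and after thinning the hypoxia libraries to control depth; 2 were called with loess offsets and with at least 50 counts in 3 libraries, a filter the deeper hypoxia libraries can meet alone. There were 5 calls (4 higher, 1 lower) with counts halved to pairs, 14 (11 and 3, of 25,549 tested) with the default filter on pairs, 5 (3 and 2) with the unpaired share as a covariate, 8 (5 and 3) in the strongest 1% alone and 27 (17 and 10) with limma-voom. Leaving out 1 library gave 0 to 25 calls (25 without control 2), with 52% to 100% of them higher. DESeq2 size factors and total counts gave 1 call each. Against 0 windows, 3 passed with loess offsets, 10 with the unpaired share (9 higher, 1 lower) and 1 with windows of 20 numbers; leaving out 1 library gave 0 to 15. Against 0 runs, 3 passed under DESeq2 and 12 with the unpaired share (5 higher, 7 lower); leaving out 1 library gave 0 to 30. Fewer peaks tested accounts for part of the rise under stricter filters; the cause of the other changes was not tested. The within-group excess in correlation was 0.0200 with Spearman and no thinning. The median log2 fold change of the strongest 1% stayed below 0 in all 20 settings, at -0.01 with loess offsets, and from -0.16 to -0.04 when leaving out 1 library. The stricter adjusted p and the test against 1.5-fold kept the main fold changes, so they could not move it. Loess offsets by mean signal pull it toward 0 by design. A_120271, A_41666, A_64827 and A_24676 kept their direction in each setting that tested them. They were chosen for a small p in these same libraries, so this is no independent support.

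Deviations of same-numbered libraries from their group mean correlated at -0.017, 0.014 and 0.016 across single peaks. Counting noise may hide a shared effect at that level, so these values cannot decide whether the numbers pair the samples. With the replicate number as a block 0 peaks were called (6013 at an unadjusted p under 0.05), 0 with loess offsets added, and 2 windows and 4 runs passed. Depth limits most single peaks: with 67 peaks changed 2-fold in each simulation, 4.48% were called over all peaks and 65.7% in the strongest 1%. Tests of gene lists, promoters, motifs, chromosomes, width and GC content were not run.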

Other observations

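Tests of the even counts, of whole windows and of the library order were chosen after the results were seen; so were the counts of splits for windows, runs and the strongest 1%, and the simulation of windows, while the count of splits and the simulation for single peaks and the chi-square were not.

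Counts came in steps of 2. Reads counted singly are argued against, since the even share lay at least 13.8 percentage points above what such reads give, in every library. A candidate explanation is that each fragment added 2 to a count: the lowest even share was 63.8%, and the share fell toward 50.0% in peaks of 100 counts or more, where stray single reads add up. The chi-square between libraries averaged 2.36 per peak over 15 pairs, so most of the spread between libraries may be counting noise of pairs, and the common dispersion was 0.013 on halved counts against 0.0908 on counts as deposited. The labels name single-end reads, so how 2 counts per fragment arose stays open, as does any biological explanation, which was not tested; if it holds, a library rests on 852,252 to 1,817,218 fragments in peaks.

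Few peaks passed between hypoxia and control. Changes of whole windows by 1.5-fold or more against the rest of the table, hidden by low counts per peak, are argued against. The smallest adjusted p over windows was 0.185 by edgeR, and no window went beyond a log2 fold change of 0.35. Of 67 windows simulated at 1.5-fold, 100% were called. Low counts per peak stay open as a candidate explanation for single sites, since 4.48% of simulated 2-fold changes were called. The real split called 1 peak and the highest other split 2, so 2 of the 10 splits gave as many, as did 3 for the strongest 1% tested alone (real 8, highest other 20) and, by construction, all 10 for windows (real 0, highest other 191) and runs (real 0, highest other 18); 10 splits cannot give a share under 0.05, and the share of peaks with an unadjusted p under 0.05 was higher in the real split (5.61%) than in the highest other (4.89%), as in the strongest 1% (12.1% and 11.7%) but not in windows (11.0% and 24.7%). For these shares the highest other split was each time the one with control 2 and hypoxia 3 exchanged. In windows every remaining split gave 4.07% or less. A small or local response to 1% oxygen stays open. A change shared by all peaks stays open too, since every setting first scaled the libraries to each other, which removes it. Sequencing depth, 1.77 times higher on average in hypoxia, cannot be separated from the group.

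The libraries ordered across the groups in windows of neighbouring peak numbers. With control 2 and hypoxia 3 exchanged, 191 windows passed (121 and 70), which points to a structure of the samples other than the given groups; counting noise of single windows is argued against, since fold changes of neighbouring windows under that split correlated at 0.451, against 0.283 under the given labels. A library property marked by the unpaired share is a candidate explanation: it separates the same 3 libraries from the other 3, and 31 windows followed it with the group in the model (10 and 21). The unpaired share is not the only such marker. The share of counts in the strongest 1% of peaks separates the same libraries, at 13.589% or more against 13.125% or less. The unpaired share was chosen after the results were seen and parts the libraries as that split does. The 31 windows are therefore no independent support for such a property. Exchanged labels of control 2 and hypoxia 3 cannot be told apart from it, as the 191 windows come from the same split, and the other values are mixed. Depth follows the labels (1,704,504 counts in control 2 and 3,061,636 in hypoxia 3). So do measures not corrected for depth (even share 82.0% and 63.8%, peaks with 0 counts 3.38% and 0.556%, and the third principal component of the peaks). The within-group excess in correlation at equal depth is higher for the given labels (0.0113) than for any other split (0.00777 or less). Pair by pair at equal depth, hypoxia 3 correlated at 0.461 and 0.441 with control 1 and 3 and at 0.455 and 0.431 with hypoxia 1 and 2. Control 2 correlated at 0.423 and 0.400 with control 1 and 3 and at 0.410 and 0.384 with hypoxia 1 and 2. In the strongest 1% of peaks, without thinning, hypoxia 3 correlated at 0.967 and 0.965 with hypoxia 1 and 2 and at 0.951 and 0.948 with control 1 and 3. In those peaks control 2 correlated at 0.945 and 0.929 with control 1 and 3 and at 0.949 and 0.951 with hypoxia 1 and 2. With the unpaired share as a covariate 10 windows and 12 runs differed between hypoxia and control. That covariate takes the axis seen in these same windows out of the spread between libraries. More calls can follow from this alone, so they do not decide whether neighbouring peak numbers responded, which stays open. GC content, copy number and replication timing were not tested.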
